A study of Rattus norvegicus with 20 samples.

How the data were processed

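RNA of small vessels dissected from rat kidneys was measured in 20 libraries, 5 rats in each of 4 groups. The rats were Dahl salt-sensitive (SS) males, or SS males labelled as carrying a null mutation of Ccl2, kept for 2 weeks on chow with 0.3% or 4.0% NaCl. Per the labels, RNA was extracted with TRIzol, treated with DNase I and selected for poly A before library preparation. Per the submitters' processing notes, the tools included Trim Galore, MultiQC, STAR 2.7.11b, featureCounts 2.0.6 from Subread and DESeq2 1.44, with the rat build mRatBN7.2. The settings of these tools are not given in the sources used here.

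The deposited table holds the authors' normalized counts, a signal per gene and library in which read counts were divided by a factor for each library. It has 16672 rows, of which 15543 have a gene name and 1129 have only an identifier. Dividing each library by its smallest positive value gave whole numbers for 100% of values within 1e-06, so the reads behind the deposited signal could be recovered. The libraries held 22.0 to 47.9 M recovered reads, with a mean of 31.2 M. Every listed gene had at least 100 recovered reads summed over the 20 libraries, so rarer transcripts could not be assessed. Gene names are those of the table. A RefSeq name table of another rat assembly, GRCr8, holds 14827 of these names, and no coordinates were taken from it.

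The test of each gene was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend) on log2 of the deposited signal plus 1. All 20 libraries entered 1 fit of 4 group means, so the groups shared an estimate of the spread. Genes with a normalized count of at least 10 in at least 5 libraries were tested, which left 16153 and removed 519. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05, and every adjusted p for a gene is from limma. Fold changes are on the log2(value + 1) scale, which understates changes of rare transcripts. Errors after ± are standard errors for log2 fold changes and SDs for levels.

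There were 5 comparisons: 4.0% against 0.3% NaCl in SS rats, the same in rats labelled null, null against SS on each diet, and the interaction, which is the salt effect in null rats minus that in SS rats. The level of Ccl2 was compared between genotypes within each diet by a two-sided exact permutation test over the 126 ways of dividing 10 rats. The labels number the rats within a group, and nothing in them ties a number to a litter or a day.

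Before the data were examined, 39 gene lists (cell type markers and pathways), the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 tested members, 36 in all, were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test was run with the correlation estimated from the data. Some lists share genes, such as Vcam1, Timp1 and Spp1, so their results are not independent. Genes are named as follows: Ccl2 and Ccr2 always; in each comparison the 8 higher and 8 lower genes with the largest fold change among those past the threshold with a mean of at least 50 (for the interaction, the 8 smallest p); up to 4 members of smallest p of each list described; and a set of vascular, renal and inflammatory genes fixed by name. Some genes that this rule picks are not reported here, and no other gene was put in their place. Members of the RT1, Cyp4a, Cyp2c, Klk1c and Serpina3 families and the mitochondrially encoded genes have near-identical copies in the genome, so their reads are uncertain between copies.

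The alternatives were pseudocounts of 0.5 and 8, no filter, a filter of 100, scaling to the library total, quantile normalization, a fit of the compared groups alone, library weights, the rat number as a block, a tubule score as a covariate, and leaving out each rat. The tubule score is the mean log2 signal of the proximal tubule, loop and collecting duct lists. The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM) and with DESeq2 1.42.0. Chosen after seeing the data were scaling to the total without mitochondrially encoded genes, the mitochondrial share as a covariate, and leaving out the 2 libraries farthest from their groups.

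The gene test was tried on simulated data made from the means, spreads and library sizes of these 16153 genes, with 200 genes changed. Genes were drawn independently and changed in a single group, with no shift shared across genes. The shares below may therefore not hold for the real libraries. For salt in SS, 55.2% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 93.9% of those changed 4-fold were recovered. For the interaction these shares were 26.9%, 70.1% and 92.4%. Among simulated calls for salt in SS, 7.41% were unchanged genes.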

Results

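Gene expression in dissected kidney microvessels was compared between SS rats, which develop hypertension and kidney injury on a high-salt diet, and SS rats labelled Ccl2 null, on 0.3% or 4.0% NaCl. Ccl2 is a chemokine that draws monocytes through the receptor Ccr2. The title of the study names the myogenic tone of these vessels and the part that Ccl2 plays in it. Each group had 5 rats, and sequencing depth averaged 32.6 ± 4.84 M reads in SS rats on low salt and 29.2 ± 5.90 M on high salt (SD, n = 5 each). In rats labelled null it was 34.4 ± 8.02 M and 28.6 ± 6.57 M.

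The dissected material held transcripts of tubules as well as vessels. Mitochondrially encoded transcripts took 30.2% ± 8.06 of reads in SS rats on low salt, 13.3% ± 5.98 in SS rats on high salt, 20.5% ± 5.76 in rats labelled null on low salt and 13.3% ± 2.83 in those on high salt. The marker lists of proximal tubule, loop of Henle and collecting duct took 4.18% ± 0.21, 3.24% ± 0.16, 3.75% ± 0.39 and 3.73% ± 0.20 of the remaining reads, in the same order. On the first principal components, which held 20.7% and 15.1% of the variance, rat 1 of the SS high-salt group lay apart from the other libraries on the second. Rat 4 of the null low-salt group lay apart on the third, which held 8.14%.

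**Figure D1:**
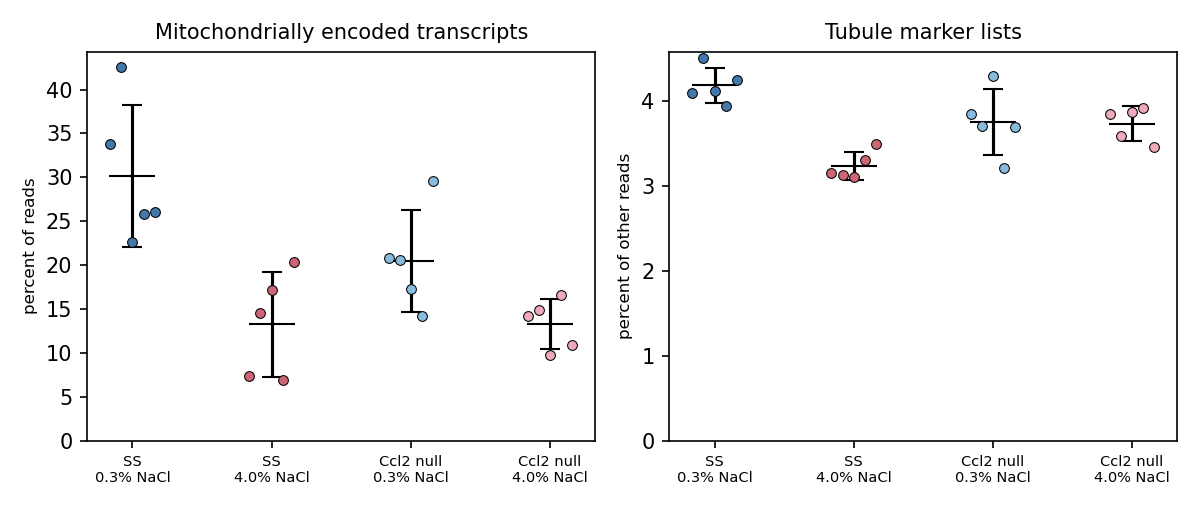
Percent of reads from mitochondrially encoded genes (left) and percent of the other reads from the tubule marker lists (right), with a point for each rat and bars for the mean and SD of 5 rats. Mitochondrial shares were 30.2% ± 8.06 in SS rats on low salt and 13.3% ± 5.98 on high salt.

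Ccl2 itself was still detected in every library labelled null. Its normalized count was 187 ± 28.5 in SS rats on low salt and 173 ± 35.4 in rats labelled null on the same diet, a log2 difference of -0.12 (exact permutation p = 0.516, two-sided, n = 5 each). On high salt it was 285 ± 113 in SS rats and 98.3 ± 21.0 in rats labelled null, a log2 difference of -1.46 (exact permutation p = 0.00794, the smallest that 5 against 5 can give). All 5 null rats on high salt, at 77.5 to 128, lay below the SS range of 167 to 426. A mutated gene can still be transcribed, so this level does not show whether the low-salt libraries labelled null came from null rats. Directions between genotypes on low salt, the salt effect in rats labelled null and the interaction rest on those labels.

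**Figure D2:**
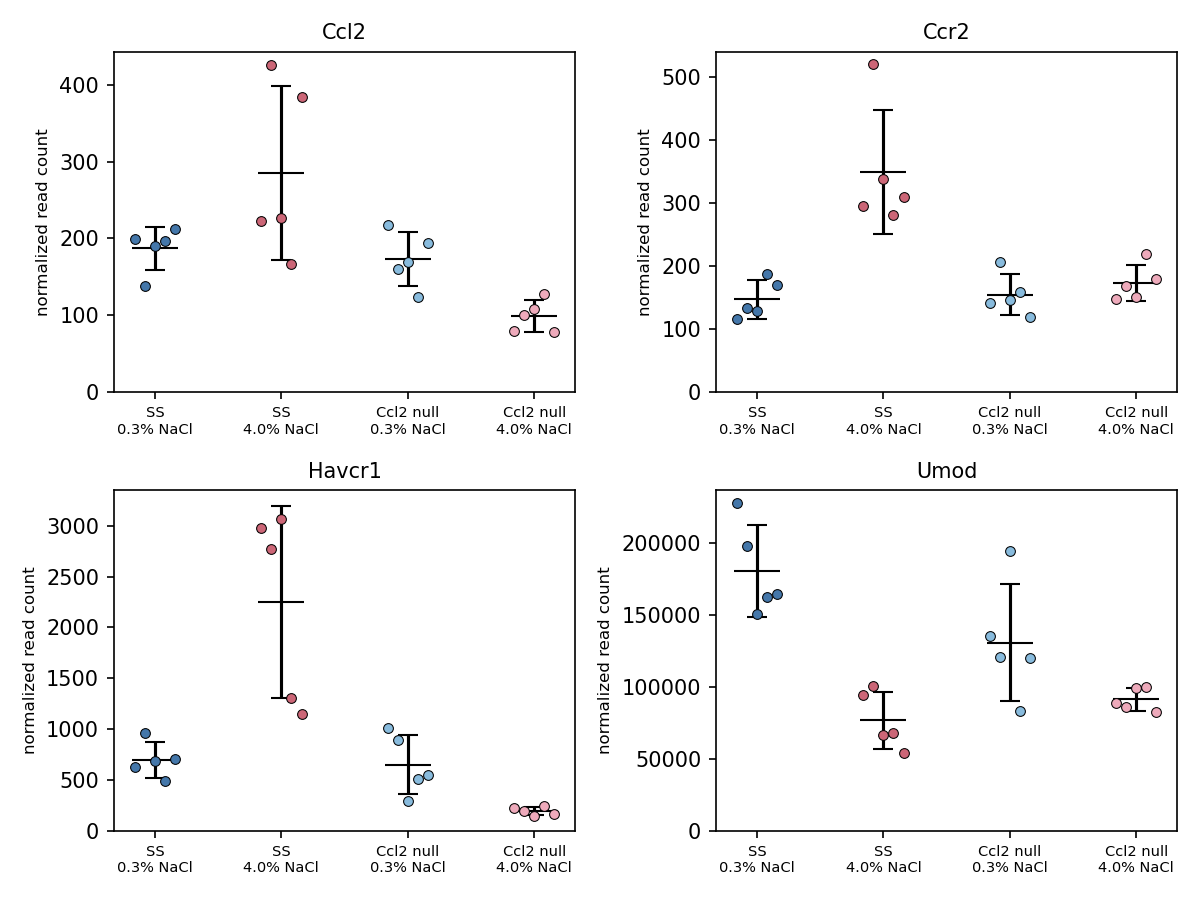
Normalized read counts of Ccl2, Ccr2, Havcr1 and Umod in each rat, with bars for the mean and SD of 5 rats per group. Ccl2 in rats labelled null was 173 ± 35.4 on low salt and 98.3 ± 21.0 on high salt.

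In SS rats, high salt raised many transcripts of T cells, macrophages, matrix and injured tubules in the microvessel preparations and lowered many of those of the distal nephron. Of 38 tested genes of extracellular matrix, 25 rose and 1 fell, and 16 of 21 T and NK cell genes, 11 of 24 macrophage genes and 10 of 11 MHC class II genes rose, but 0 of 8 B and plasma cell genes. No list passed with its correlation estimated, the lowest being adjusted p = 0.101 with an estimated correlation. Ccr2 rose from 147 ± 30.6 to 349 ± 98.3 normalized counts (log2 1.23 ± 0.18, adjusted p = 1.03e-04), while Ccl2 differed by 0.53 ± 0.22 and did not pass (adjusted p = 0.0966). The smooth muscle contractile genes Acta2 and Myh11 differed by -0.01 ± 0.14 and 0.02 ± 0.18 and did not pass.

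Among matrix genes the fibrillar collagens Col3a1 (1.24 ± 0.14) and Col5a2 (1.01 ± 0.11), the microfibrillar collagen Col6a1 (1.40 ± 0.17) and the crosslinking enzyme Loxl1 (1.14 ± 0.15) rose (list adjusted p = 4.89e-13, and adjusted p = 0.101 with an estimated correlation). Adjusted over the list alone, 28 of the 38 rose. In the fibroblast list 7 of 10 rose, among them the proteoglycan Dcn (1.39 ± 0.16), Pdgfra, a growth factor receptor (0.84 ± 0.13), Col1a2 (1.00 ± 0.15) and Col1a1 (0.82 ± 0.14; adjusted p = 0.101 with an estimated correlation). The macrophage genes Mrc1, a mannose receptor (1.70 ± 0.21), Clec10a (1.55 ± 0.16) and Gpnmb (1.49 ± 0.19) rose (list adjusted p = 1.77e-08, and adjusted p = 0.18 with an estimated correlation), while Cd68 differed by 0.27 ± 0.30 and did not pass. T cell genes that rose included Cd5 (1.14 ± 0.25), Cd2 (1.09 ± 0.23), Il7r (1.01 ± 0.21) and Cd3e (0.83 ± 0.22; list adjusted p = 1.96e-09, and adjusted p = 0.101 with an estimated correlation). Antigen presentation genes rose too, though reads of the RT1 family are uncertain between copies, with RT1-Db1 at 0.72 ± 0.11 and their regulator Ciita at 0.74 ± 0.12 (adjusted p = 0.159 with an estimated correlation).

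Of 43 chemokine genes 15 rose, among them Ccl21 (1.73 ± 0.15) and Ccr6 (1.47 ± 0.20; adjusted p = 0.101 with an estimated correlation). The adhesion molecules Icam1 (0.54 ± 0.11) and Vcam1 (0.58 ± 0.12), the latter also in the tubular injury list, rose with 3 other genes of a list of 15 (adjusted p = 0.208 with an estimated correlation). So did 8 of 26 NF-kB and cytokine genes, led by Tnfaip3 (0.68 ± 0.12, list adjusted p = 0.101 with an estimated correlation). Of 13 tubular injury genes 7 rose, among them Havcr1, the kidney injury marker (1.61 ± 0.30), Clu (1.13 ± 0.17) and the protease inhibitor Timp1 (1.05 ± 0.15; adjusted p = 0.159 with an estimated correlation). In the loop and distal tubule list 7 of 14 fell and 1, Trpv5 (0.71 ± 0.15), rose. Those that fell included Umod, the main urinary protein (-1.26 ± 0.20), the claudins Cldn16 (-1.05 ± 0.12) and Cldn10 (-0.84 ± 0.08) and the potassium channel Kcnj1 (-0.64 ± 0.09; adjusted p = 0.101 with an estimated correlation). All 13 mitochondrially encoded genes fell, by a mean of 1.75 (adjusted p = 0.18 with an estimated correlation). The steepest of them was Mt-nd2 (-2.15 ± 0.55), with Mt-atp6, Mt-cyb, Mt-nd1, Mt-nd4l and Mt-co3 between -1.95 and -1.75. Of 22 cell cycle genes 5 fell, for example Ccnb1 (-0.76 ± 0.18; adjusted p = 0.273 with an estimated correlation).

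The largest rises past the threshold and a mean of 50 were those of the transporter Abca8a (2.32 ± 0.17), the lipase inhibitor Angptl4 (2.31 ± 0.45), the neuropeptide precursor Pnoc (2.18 ± 0.48), the chemokine Cxcl14 (2.09 ± 0.37) and the proton pump Atp12a (2.00 ± 0.67). Next came the complement protein C6 (1.96 ± 0.34), the transcription factor Tbx1 (1.96 ± 0.20) and Mmrn1 (1.94 ± 0.21), a lymphatic endothelial marker. Besides the mitochondrial genes, the sodium pump subunit Atp1a4 (-2.06 ± 0.22) and the ligand Wnt2b (-1.74 ± 0.37) fell most. Among genes of vascular tone, the cation channel Trpm4 rose (0.40 ± 0.08), as did the receptors Adra2a (1.15 ± 0.28), Avpr1a (0.79 ± 0.18), Npr1 (0.55 ± 0.14) and Adra1b (0.47 ± 0.10) in a list of which 6 of 30 rose (adjusted p = 0.343 with an estimated correlation). The tubule score as a covariate turned Npr1 to -0.022 and ended the call of that list (adjusted p = 0.669), as did total scaling (adjusted p = 0.16). Of 37 myogenic genes 7 rose and 1 fell, among them the channel subunit Cacnb3 (0.65 ± 0.14), the flow sensor Pkd1 (0.50 ± 0.09) and the potassium channel Kcnq5 (-1.04 ± 0.29; adjusted p = 0.421 with an estimated correlation). The channel genes Kcnma1 (0.24 ± 0.20), Kcnmb1 (-0.10 ± 0.20), Cacna1c (0.12 ± 0.18) and Trpc6 (0.02 ± 0.23) did not pass. Neither did Nos3 (-0.04 ± 0.14), Agtr1a (0.09 ± 0.15), Ednra (0.26 ± 0.16) or the proximal tubule transporter Slc34a1 (-0.02 ± 0.12). The smooth muscle contractile list had 0 risen and 1 fallen member among 18, and its mean of -0.02 and median of 0.0036 differ in sign.

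In all, 2787 of 16153 genes changed with salt in SS rats, 1538 higher and 1249 lower, and 499 of them changed at least 2-fold. A fit with the tubule score as a covariate passed 162 genes, with the mitochondrial share as a covariate 1241, and in a fit of these 10 libraries alone 1570. Scaling to the library total gave 8929 genes, 8767 of them higher, and moved the median of all genes by 0.38, so directions here are relative to the deposited scaling.

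In rats labelled null, high salt raised genes of fatty acid use and lowered cell cycle genes and the injury marker Havcr1. Of 20 fatty acid oxidation genes 9 rose and 0 fell, and of 22 cell cycle genes 7 fell. The cell cycle list fell in SS rats too (mean -0.48). In the interaction 0 genes of either list passed. As a set the cell cycle list did not pass there (adjusted p = 0.128 at the preset correlation), while the fatty acid list did (5.05e-04). The fatty acid list did not pass there with an estimated correlation (adjusted p = 0.479) or with the tubule score as a covariate (0.608). Its mean was also above 0 in SS rats (0.27), where 2 of its genes rose. Havcr1 fell from 650 ± 294 to 195 ± 40.6 normalized counts (log2 -1.63 ± 0.30, adjusted p = 0.0042). Ccl2 fell by 0.81 ± 0.22 (adjusted p = 0.034) and Ccr2 differed by 0.17 ± 0.18 and did not pass.

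The peroxisomal enzyme Ehhadh (1.13 ± 0.24), Acaa2 (0.81 ± 0.19) and Etfdh (0.52 ± 0.11) rose (list adjusted p = 6.36e-10, and adjusted p = 0.274 with an estimated correlation). Their regulator Creb3l3 (3.92 ± 0.97) and the fatty acid hydroxylases Cyp4a3 (1.69 ± 0.26) and Cyp4a1 (1.60 ± 0.25) rose too, the hydroxylases, whose reads are uncertain between family members, being the 2 of 25 nitric oxide and prostanoid genes that rose (adjusted p = 0.274 with an estimated correlation). In the proximal tubule list 4 of 21 rose, among them Cyp2e1 (1.67 ± 0.17) and the fatty acid transporter Slc27a2 (0.99 ± 0.14), and Gatm fell (-1.07 ± 0.24; adjusted p = 0.361 with an estimated correlation). Replication genes Mcm5 (-1.29 ± 0.23), Mcm3 (-0.86 ± 0.18) and Mcm2 (-0.61 ± 0.10) and the cyclin Ccnb1 (-0.94 ± 0.18) fell (list adjusted p = 1.29e-10, and adjusted p = 0.274 with an estimated correlation). In the tubular injury list Havcr1, Lcn2 (-0.82 ± 0.23) and Cd44 (-0.65 ± 0.19) fell among 13 (adjusted p = 0.404 with an estimated correlation). Interferon response genes fell in 5 of 22 cases, including the antiviral Oasl (-0.91 ± 0.18) and Gbp5 (-0.52 ± 0.13; adjusted p = 0.32 with an estimated correlation), and the chaperones Hsph1 (0.83 ± 0.20), Dnaja1 (0.71 ± 0.17) and Bag3 (0.35 ± 0.08) rose among 10 (adjusted p = 0.274 with an estimated correlation).

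Vascular genes that rose were the potassium channel subunit Abcc9 (1.17 ± 0.25), the mechanosensitive channel Trpv4 (0.34 ± 0.09), the calcium release channel Itpr1 (0.28 ± 0.07) and the calcium pump Atp2a2 (0.31 ± 0.09), making 4 of 37 myogenic genes (adjusted p = 0.274 with an estimated correlation). Of 30 vasoactive receptor genes 3 rose, the adrenergic receptors Adra1a (0.62 ± 0.15) and Adra1b (0.56 ± 0.10) and the endothelin receptor Ednrb (0.63 ± 0.17), and 2 fell, among them Adra1d (adjusted p = 0.033). For that list the adjusted p = 0.557 with an estimated correlation. Of 18 endothelial genes 3 rose, Flt1 (0.63 ± 0.13), Plvap (0.72 ± 0.20) and Ehd3 (0.36 ± 0.10), and Vwf fell (-0.40 ± 0.10; adjusted p = 0.557 with an estimated correlation). The lymphatic genes Mmrn1 (1.32 ± 0.21) and Ccl21 (0.80 ± 0.15) rose, Ccl21 by less than in SS rats (adjusted p = 0.274 with an estimated correlation). Other large changes were those of Atp12a (2.90 ± 0.67), Vnn1 (1.89 ± 0.30), Cntfr (1.87 ± 0.40) and Fam180a (1.75 ± 0.42) upward. Downward they were those of the carbonic anhydrase Car3 (-2.04 ± 0.39), Mybpc2 (-1.69 ± 0.22), the calcium binder Calb1 (-1.63 ± 0.14), Hao1 (-1.50 ± 0.23), the mitotic genes Cdkn3 (-1.46 ± 0.35) and Kif4a (-1.40 ± 0.30) and Sphkap (-1.42 ± 0.36). Of the mitochondrially encoded genes only Mt-nd3 passed (-0.88 ± 0.26), and the mean of the 13 was -0.77 (adjusted p = 0.434 with an estimated correlation).

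With salt 891 genes changed in rats labelled null, 495 higher and 396 lower. Total scaling moved the median of all genes by 0.12, and most genes that passed were then higher. In a fit of these 10 libraries alone the count was 2053, and with library weights 2628. Genes whose low-salt and high-salt values did not overlap numbered 1741, against 1505 for salt in SS. The smaller count of 891 therefore does not by itself show a weaker salt response. Leaving out 1 rat gave 540, 564 and 469 without null low-salt rats 3 to 5, 531, 517, 485 and 419 without null high-salt rats 2 to 5, and 1609 without SS high-salt rat 1.

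**Figure D3:**
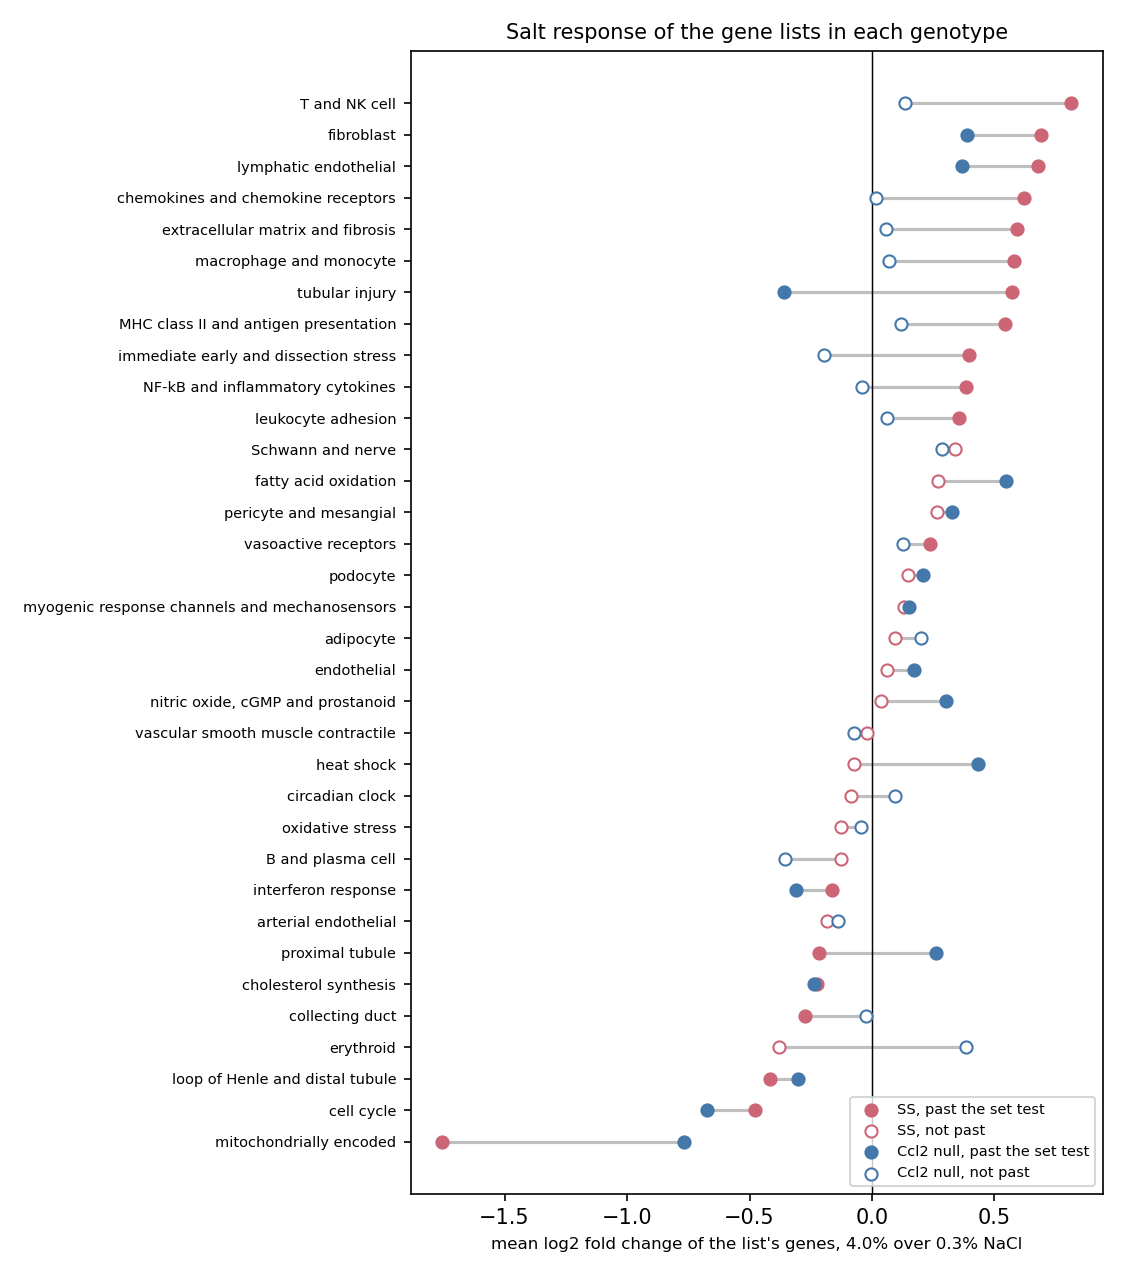
Mean log2 fold change of tested gene lists with high salt, in SS rats (red) and rats labelled null (blue), 5 rats per group; filled points passed the set test at a preset correlation of 0.01. The T and NK cell list stands at 0.81 in SS rats and 0.14 in rats labelled null, and the tubular injury list at 0.57 and -0.36.

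The salt responses of the genotypes, which share no library, overlapped in direction. Of the changed genes 192 were higher in both and 139 lower in both, where independent lists would share 47.1 and 30.6, and 15 and 2 went opposite ways, where 37.7 and 38.3 would. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.27 with a jackknife error of 0.14, at 0.20 to 0.36 without single rats, and at 0.46 with the mitochondrial share as a covariate.

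The interaction compares those salt effects directly, and most genes that differed had a lower salt effect in rats labelled null. Havcr1 had the smallest p: its interaction was -3.24 ± 0.42 (adjusted p = 9.9e-04). Ccl2 (-1.34 ± 0.31) and Ccr2 (-1.06 ± 0.25) also differed, with adjusted p = 0.024 and 0.028. Of 13 tubular injury genes 6 were lower, and of 24 macrophage genes 5.

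After Havcr1 came the spectrin Sptbn4 (-1.92 ± 0.25), the complement protein C4b (-2.22 ± 0.30), Tbx1 (-1.99 ± 0.29), Timp1 (-1.46 ± 0.21), the chemokine receptor Ccr6 (-1.95 ± 0.29), the T cell kinase Zap70 (-1.51 ± 0.23) and Ephb6 (-1.90 ± 0.29). In the injury list Lcn2 (-1.57 ± 0.32) and Clu (-1.21 ± 0.24) were lower too (list adjusted p = 3.15e-08, and adjusted p = 0.13 with an estimated correlation). In the matrix list 7 of 38 were lower, including the glycoprotein Tnc (-2.11 ± 0.44), Col15a1 (-1.31 ± 0.23) and Lgals3 (-0.82 ± 0.18), and 17 when adjusted over the list alone (adjusted p = 0.225 with an estimated correlation). Among leukocyte genes Gpnmb (-1.66 ± 0.27), Trem2 (-1.38 ± 0.32), Clec10a (-1.30 ± 0.22), Cd8b (-1.57 ± 0.40) and Cd3d (-1.52 ± 0.41) were lower, the macrophage and T cell lists each having adjusted p = 0.25 with an estimated correlation. Of 43 chemokine genes 6 were lower, among them Ccl21 (-0.94 ± 0.22; adjusted p = 0.214 with an estimated correlation). The endothelial selectins Selp (-1.39 ± 0.30) and Sele (-1.25 ± 0.33) were lower among 3 of 15 adhesion genes (adjusted p = 0.474 with an estimated correlation), as were Birc3 (-1.15 ± 0.26), Tnfaip3 (-0.84 ± 0.17) and Relb (-0.74 ± 0.20) of the NF-kB list (adjusted p = 0.13 with an estimated correlation). RT1-Db1 (-0.70 ± 0.16) and Ciita (-0.68 ± 0.17) were lower among 3 of 11 antigen presentation genes (adjusted p = 0.25 with an estimated correlation). Proximal tubule genes Slc7a13 (1.66 ± 0.38) and Kap (1.42 ± 0.30) were higher (adjusted p = 0.25 with an estimated correlation), as were the phosphodiesterase Pde1a (0.63 ± 0.14) and Cyp4a8 (1.07 ± 0.25; adjusted p = 0.25 with an estimated correlation). Trpm4 was lower (-0.44 ± 0.12, adjusted p = 0.048). Lists tied to the handling of tissue moved as well. The immediate early and dissection stress list was lower (mean -0.59, adjusted p = 0.00845, and adjusted p = 0.571 with an estimated correlation), with Egr2 past the threshold. Its call was lost with the tubule score (adjusted p = 0.452), with total scaling (0.0502) and without null low-salt rat 5 (0.0507) or SS high-salt rat 3 (0.132). The heat shock list was higher (mean 0.51, adjusted p = 6.16e-05, and adjusted p = 0.25 with an estimated correlation). So was the mitochondrially encoded list (mean 0.99, adjusted p = 2.21e-04, and adjusted p = 0.479 with an estimated correlation). The mitochondrial call was lost with quantile normalization (adjusted p = 0.0936) and with the mitochondrial share as a covariate (0.371). That share is summed over the mitochondrially encoded genes themselves, so the loss with it was built in.

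In all 409 genes had a different salt effect, 125 higher and 284 lower in rats labelled null. Total scaling moved the median of all genes by -0.27, and nearly all genes that passed were then lower. Directions here are thus relative to the deposited scaling. With the tubule score as a covariate 0 genes passed in limma, with 958 at an unadjusted p under 0.05, against 2906 in the main fit. Chance alone would put about 0.05 of the 16153 tested genes there. Without that score edgeR gave 439 and DESeq2 835. The score also ended the set calls of the leukocyte adhesion (adjusted p = 0.442), proximal tubule (0.984), fibroblast (0.0588) and nitric oxide, cGMP and prostanoid lists (0.0882), the last being that of Pde1a and Cyp4a8. The score is made in part from the proximal tubule genes, so the loss of that call was largely built in. Without single rats 221 to 612 passed: 260 and 221 without null low-salt rats 4 and 5, 224, 237 and 267 without null high-salt rats 1, 4 and 5, and 237 without SS high-salt rat 2.

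On high salt, rats labelled null had less of the injury and antigen presentation transcripts and of some macrophage transcripts than SS rats, and more of some endothelial and pericyte ones. The endothelial and pericyte lists were shifted upward on low salt too. Havcr1 was lower by a log2 of -3.43 ± 0.30 (adjusted p = 1.1e-06), with 9 of 13 tubular injury genes lower. Ccl2 (-1.46 ± 0.22, adjusted p = 4.7e-04) and Ccr2 (-0.98 ± 0.18, adjusted p = 0.0022) were lower. Lists tied to tissue handling and the circadian clock moved as well at the preset correlation. The immediate early and dissection stress list was lower (mean -0.52, adjusted p = 0.00368). The heat shock list (mean 0.39, adjusted p = 8.79e-04) and the circadian clock list (mean 0.43, adjusted p = 0.0044) were higher. None passed with an estimated correlation.

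The injury genes Spp1 (-1.84 ± 0.24), Lcn2 (-1.81 ± 0.23) and Timp1 (-1.23 ± 0.15) were lower (list adjusted p = 3.23e-12, and adjusted p = 0.0602 with an estimated correlation). Of 24 macrophage genes 7 were lower and 1 higher. Among those lower were Gpnmb at -1.43 ± 0.19, Clec10a at -1.24 ± 0.16 and the lipid receptor Trem2 at -1.06 ± 0.22 (adjusted p = 0.458 with an estimated correlation). With the tubule score as a covariate the set tests of the macrophage list (adjusted p = 0.0515) and the T and NK cell list (adjusted p = 0.308) no longer passed. The T and NK cell call was also lost with the filter of 100 (adjusted p = 0.0769). The same held without null high-salt rat 1 (0.0758), or without SS high-salt rats 2 (0.105) or 4 (0.0565). The T cell genes Cd3d (-1.02 ± 0.29), Cd8b (-0.91 ± 0.28), Cd5 (-0.87 ± 0.25) and Cd3e (-0.69 ± 0.22) were lower (adjusted p = 0.458 with an estimated correlation). MHC class II genes were lower in 7 of 11 cases, RT1-Db1 by -0.74 ± 0.11 and RT1-Da by -0.66 ± 0.10 (adjusted p = 0.246 with an estimated correlation). Ccr6 (-1.82 ± 0.20) was lower and Ccl3 (1.36 ± 0.20) higher in the chemokine list (adjusted p = 0.391 with an estimated correlation), and Lif (-1.37 ± 0.26), Birc3 (-1.06 ± 0.18) and Il34 (-0.79 ± 0.13) were lower in the cytokine list (adjusted p = 0.246 with an estimated correlation).

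Endothelial genes Cdh5, the junction cadherin (0.60 ± 0.15), Tek (0.58 ± 0.14), Flt1 (0.54 ± 0.13) and Tie1 (0.38 ± 0.11) were higher, 5 of 18 in all (adjusted p = 0.348 with an estimated correlation). Pericyte genes Abcc9 (0.90 ± 0.25), Rgs5 (0.82 ± 0.19), Notch3 (0.80 ± 0.15) and Mcam (0.50 ± 0.14) were higher among 9 (adjusted p = 0.246 with an estimated correlation). The endothelial list had a mean of 0.32 here and 0.20 on low salt, and the pericyte list 0.48 and 0.42. Neither list passed in the interaction (adjusted p = 0.128 and 0.565 at the preset correlation), so these differences are not shown to be particular to high salt. Of 37 myogenic genes 7 were higher, among them the calcium release channel Ryr2 (0.78 ± 0.21), the potassium channel Kcnj2 (0.65 ± 0.15) and Trpv4 (0.37 ± 0.09), and the calcium channel subunit Cacnb3 was lower (-0.56 ± 0.14; adjusted p = 0.222 with an estimated correlation). The endothelin receptor Ednra (0.53 ± 0.16) was higher. The water channels Aqp3 (0.77 ± 0.12) and Aqp2 (0.64 ± 0.18) and the sodium channel subunit Scnn1g (0.55 ± 0.15) were higher in the collecting duct list (adjusted p = 0.246 with an estimated correlation).

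Large differences upward were those of Cyp2c11 (2.63 ± 0.38), the organic anion transporter Slco1a1 (1.60 ± 0.28), Klk1c4 (1.55 ± 0.34), the chloride channel Cftr (1.55 ± 0.40) and Mlc1 (1.48 ± 0.38). Downward they were those of Car3 (-3.45 ± 0.39), Pnoc (-3.18 ± 0.48), the cytokines Il24 (-2.79 ± 0.44) and Il19 (-2.59 ± 0.46), the complement regulator Cfi (-2.33 ± 0.30), Serpina3a (-2.31 ± 0.33) and Tnc (-2.18 ± 0.31).

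On high salt 1376 genes differed between the genotypes, 598 higher and 778 lower in rats labelled null. In a fit with the tubule score as a covariate 229 passed, and with total scaling 592. Leaving out 1 rat gave 850, 714 and 753 without null high-salt rats 2, 4 and 5, and 612 and 893 without SS high-salt rats 1 and 2.

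On low salt the libraries labelled null differed from those of SS rats in few genes, some of them collagens and other matrix transcripts that were higher. Col6a1 (0.91 ± 0.17), Col1a2 (0.74 ± 0.15), Col1a1 (0.68 ± 0.14), Col5a1 (0.61 ± 0.12) and Col5a2 (0.61 ± 0.11) were among 9 of 38 matrix genes that were higher, or 18 when adjusted over the list alone (list adjusted p = 7.05e-09, and adjusted p = 0.312 with an estimated correlation). Ccl2 (-0.12 ± 0.22) and Ccr2 (0.07 ± 0.18) did not pass, with adjusted p = 0.81 and 0.87.

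Higher genes with large differences were Tbx1 (1.27 ± 0.20), Aox1 (1.10 ± 0.20), Abca8a (1.10 ± 0.17), Cyp4f37 (1.09 ± 0.25), the adhesion protein Svep1 (1.07 ± 0.21), Gal3st4 (1.04 ± 0.18) and Abca8 (1.03 ± 0.20). Lower genes were the peptide hormone Apela (-0.90 ± 0.19), RT1-Hb-ps1 (-0.65 ± 0.14), Gstm1 (-0.58 ± 0.13), Nop10 (-0.48 ± 0.10), Ndufs6l1 (-0.45 ± 0.09), Cystm1 (-0.45 ± 0.08), Gpc3 (-0.45 ± 0.10) and the claudin Cldn10 (-0.42 ± 0.08). Among genes of vessel mechanics the mechanosensitive channel Piezo1 (0.41 ± 0.09) and the guanine nucleotide exchange factor Arhgef1 (0.36 ± 0.08) were higher. The myogenic list (mean 0.23) and the smooth muscle contractile list (mean 0.22, with 0 of 18 genes past the threshold) were each shifted upward at the preset correlation (adjusted p = 0.312 and adjusted p = 0.461 with an estimated correlation). The smooth muscle call was lost with the tubule score as a covariate (adjusted p = 0.112). Ccl21 (0.71 ± 0.15) was higher in the chemokine list (adjusted p = 0.353 with an estimated correlation). The T and NK cell list (mean 0.41, adjusted p = 7.16e-05) and the macrophage list (mean 0.19, adjusted p = 0.00392) were shifted upward too, with 0 genes past the threshold in limma (adjusted p = 0.353 and adjusted p = 0.505 with an estimated correlation). The macrophage call was lost with the tubule score (adjusted p = 0.0756), with total scaling (0.0804) and without SS low-salt rats 2 (0.135) or 3 (0.0584). For the T and NK cell list this low-salt difference makes up more of the interaction mean of -0.68 than the high-salt difference of -0.27 does. The same holds for the matrix list (0.31 on low salt, -0.23 on high salt, -0.54 for the interaction), the fibroblast list (0.37, 0.07 and -0.30) and the mitochondrially encoded list (-0.83, 0.15 and 0.99). For these 4 lists in the interaction, the lowest was adjusted p = 0.225 with an estimated correlation.

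On low salt 90 genes differed, 73 higher and 17 lower. With the tubule score as a covariate 0 passed in limma, with 1503 at an unadjusted p under 0.05, against 2905 in the main fit. Without that score edgeR gave 63 and DESeq2 555, and total scaling gave 4059. Leaving out 1 rat gave 1, 161, 5 and 0 without null low-salt rats 2 to 5, 54 and 55 without null high-salt rats 3 and 5, 29, 53, 4 and 397 without SS low-salt rats 1 to 4, and 373 without SS high-salt rat 1.

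At the preset correlation 19 lists passed for salt in SS (12 up, 7 down) and 16 for salt in rats labelled null (10 up, 6 down). For the other comparisons 19 passed for genotype on high salt (10 up, 9 down), 16 for genotype on low salt (13 up, 3 down) and 17 for the interaction (7 up, 10 down). With an estimated correlation 0 lists passed camera in any comparison, with 9, 5, 5, 5 and 7 lists at an unadjusted p under 0.05 in that order. Some other splits of the rats gave as many lists at the preset correlation, so these counts do not exclude chance. The median of the other splits was 11, 8, 11, 8 and 9 lists in that order. Passing at the preset correlation therefore says little by itself.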

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

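Of the tests in this part, that of total scaling for the mitochondrial transcripts was chosen only after the result was seen, and so was the mitochondrial share as a covariate. An interaction test found a different salt effect between the genotypes in 409 genes, and in 66 of the named genes. The set test passed 17 lists at the preset correlation but 0 with an estimated correlation (lowest adjusted p 0.13). Chance is not excluded for that count or for the 409 genes. The differences below are null minus SS on the log2 scale. For injury and matrix genes the difference was -3.24 for Havcr1, -1.52 for Spp1, -1.57 for Lcn2, -1.46 for Timp1, -1.24 for Cd44, -1.21 for Clu, -2.11 for Tnc, -1.31 for Col15a1, -1.01 for Loxl1, -0.82 for Lgals3 and -0.79 for Col3a1. For leukocyte genes the difference was -1.66 for Gpnmb, -1.57 for Cd8b, -1.52 for Cd3d, -1.51 for Zap70, -1.38 for Trem2, -1.30 for Clec10a, -1.14 for Cd3g, -1.06 for Ccr2, -1.01 for Icos, -0.70 for RT1-Db1, -0.68 for Ciita and -0.52 for RT1-DMa. For chemokine, adhesion and cytokine genes the difference was -2.52 for Il24, -1.95 for Ccr6, -1.39 for Selp, -1.34 for Ccl2, -1.25 for Sele, -1.15 for Birc3, -1.003 for Itgam, -0.94 for Ccl21, -0.84 for Tnfaip3 and -0.74 for Relb. For vascular and signalling genes the difference was -1.80 for Adra1d, -0.96 for Cacnb3, -0.45 for Arhgef1, -0.44 for Trpm4, 0.54 for Trpv4, 0.63 for Pde1a and 1.07 for Cyp4a8. For tubule genes the difference was 1.66 for Slc7a13, 1.42 for Kap, 0.93 for Slc12a1, 0.80 for Egf, 0.66 for Aqp3, 0.63 for Cldn16, 0.59 for Cldn10, 0.57 for Kcnj1, -0.81 for Calb1 and -1.18 for Trpv5. For other genes of large effect the difference was -3.41 for Car3, -2.60 for Cfi, -2.22 for C4b, -2.17 for Serpina3a, -1.99 for Tbx1, -1.92 for Sptbn4, -1.90 for Ephb6, -1.76 for Egr2, -1.43 for Hao1 and -1.22 for Abca8a. For the remaining genes the difference was 0.47 for Cystm1, 1.22 for Atp1a4, 1.46 for Gclc, 1.96 for Slco1a1, 2.25 for Cftr and 2.42 for Cyp2c11.

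The spread within groups was checked for 19 genes fixed by name and 3 measures of the libraries. In 4 of 88 groups a rat lay far from the other 4 of its group, where chance gives about 1 in 20, or 4.4. Ccr2 was at 520.3 in SS high-salt rat 2, against 280.7 to 338 in the others. Cacna1c was at 103.6 in SS high-salt rat 1, against 190 to 222. Trpc6 was at 78.1 in SS low-salt rat 4, against 32.6 to 44.9. Agtr1a was at 2023 in null high-salt rat 2, against 1781 to 1839.

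Groupings of rats other than the real one were tried for each count. In each comparison only 1 of 100 splits drawn, the real one, gave as many genes, the smallest share these draws allow. The counts were 2787 for salt in SS against at most 1861, 891 for salt in null against 4, and 1376 for genotype on high salt against 41. These values argue against chance for those counts. For genotype on low salt the count was 90 against 6, but it was 0 to 397 without single rats. For the interaction it was 409 against 395, which is close, and 221 to 612 without single rats. Chance is therefore not excluded for either count, nor for the list counts. The real one included, 6 of 100 splits gave as many as the 19 lists for salt in SS (highest other 22), 6 the 16 for salt in null (17), 7 the 19 for genotype on high salt (23), 17 the 16 for genotype on low salt (21) and 9 the 17 for the interaction (21).

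The lower salt effect in rats labelled null was followed in the 209 genes of the 10 lists that were lower in the interaction, whose median interaction was -0.43 with a jackknife error of 0.13. These lists were picked by that interaction in the same libraries, so a median below 0 is no evidence by itself. Only its change between settings is read here. Without SS high-salt rat 1 the median was -0.44, and with the mitochondrial share as a covariate it was -0.41, both beyond 0.5 of the main value (-0.21) by more than the error, which argues against either as the whole cause. With the tubule score as a covariate the median was -0.31, the median standard error of a gene grew from 0.27 to 0.36, and the genes past the threshold went from 34 to 0, against 32 without that rat and 19 with the mitochondrial share (median standard error 0.29). That lies within the error of 0.5 of the main value, and the score itself differs between groups (13.02 in SS on low salt, 12.7 on high salt, 12.9 in null on either diet), so tubule content in the dissected material and the genotype cannot be told apart for these genes. The handling of the tissue was not tested, though the immediate early and dissection stress list is 1 of the 10, and an effect of the genotype itself stays open.

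The fall of mitochondrially encoded transcripts with salt in SS rats was weighed next. After scaling to the library total their mean change was -1.36 ± 0.41 (standard error over rats), which restates the lower share of reads, a share that no size factor enters, and argues against the size factors as the whole cause. The 95 nuclear genes of the respiratory chain had a median of -0.34, with 50 lower and 0 higher, against -0.88 for 0.5 of the change of the mitochondrial genes. That gap of 0.53 ± 0.30 over rats argues only weakly against a loss of mitochondria, or of cells rich in them, as the whole cause, and part of the fall may come from it. RNA quality and the handling of the tissue were not tested, and an effect of the diet stays open as untested.

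Ccl2 reads in null rats on low salt, at the level of SS rats, could come from mislabelled null low-salt libraries. The test was a score of the 996 genes that differed between the genotypes in the high-salt libraries alone, and mislabelling was predicted to put at most 1 of the 5 libraries above the highest SS low-salt library. It put 1 of 5 there, with means of 0.017 ± 0.10 in null and -0.0011 ± 0.083 in SS, so mislabelled null low-salt libraries are not argued against. Differences seen on high salt need not be present on low salt, so this result would also arise with correct labels and a transcript kept on the mutated allele, which was not tested.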

How the results depend on the processing

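Chosen after seeing the data were the total without mitochondrially encoded genes, the mitochondrial share as a covariate and leaving out SS high-salt rat 1 with null low-salt rat 4; the other alternatives were planned. Where no cause is named, the cause was not tested. Pseudocounts and filters left each count within 1.5 times its main value, and so did every alternative for the 5 counts of lists, though not always for the same lists. The tubule score ended the call of 8 of 19 lists for genotype on high salt (macrophage, adjusted p 0.0515, T and NK cell 0.308, collecting duct 0.497), 8 of 17 for the interaction (fibroblast 0.0588, leukocyte adhesion 0.442), and 5 each for salt in SS and genotype on low salt. Losing proximal tubule or collecting duct calls was largely built in, as the score is made from those lists and the loop list. With the tubule score as a covariate 162 genes passed for salt in SS, 229 for genotype on high salt, 0 for genotype on low salt and 0 for the interaction. At an unadjusted p under 0.05 in limma there were 1503 for genotype on low salt, against 2905 without the score. For the interaction there were 958, against 2906. Total scaling gave 8929 for salt in SS (8767 higher and 162 lower, against 1538 and 1249), 592 for genotype on high salt, 4059 for genotype on low salt (4053 higher, against 73 of 90) and 1082 for the interaction (29 higher, against 125 of 409). It moved the median of all genes by 0.38, 0.12, 0.0022, 0.26 and -0.27 in the order of the comparisons, and for salt in null 918 of 1031 genes were then higher, against 495 of 891. Scaling without mitochondrial genes gave 368 for genotype on low salt, and 2148 of 2870 genes higher for salt in SS. In a fit of the compared groups alone, which estimates the spread from those groups only, 1570 genes passed for salt in SS, 2053 for salt in null and 28 for genotype on low salt. Group means, and so fold changes, are the same in that fit, so these counts moved through the estimate of the spread. The library weights are larger for libraries nearer their group mean. They were 1.03 to 1.99 in null high-salt rats and 0.26 to 1.07 in SS high-salt rats. Library weights gave 2628 for salt in null and 487 for genotype on low salt, and quantile normalization gave 57 for the latter. DESeq2 gave 1656 for salt in null, 555 for genotype on low salt and 835 for the interaction, and 3336 and 2030 for the others; edgeR gave 2793, 956, 1441, 63 and 439. With the mitochondrial share as a covariate 1241, 1571, 404 and 242 genes passed for salt in SS, salt in null, genotype on low salt and the interaction, and the correlation of salt effects was 0.46. Without the 2 outlying libraries 851 passed for genotype on high salt and 237 for the interaction.

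The rat numbers do not pair the rats: same-numbered deviations correlated at -0.16 to 0.14, and 2 of 20 libraries matched their own number best. With the number as a block 2618, 814, 1276, 132 and 275 genes passed, and the Ccl2 difference on high salt had an exact p of 0.0625 at -1.46, the smallest that 5 pairs allow.

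Leaving out 1 rat gave 419 to 1609 genes for salt in null: 540, 564 and 469 without null low-salt rats 3, 4 and 5, 531, 517, 485 and 419 without null high-salt rats 2 to 5, and 1609 without SS high-salt rat 1. For genotype on high salt it gave 612 to 1798: 850, 714 and 753 without null high-salt rats 2, 4 and 5, and 612 and 893 without SS high-salt rats 1 and 2. For genotype on low salt it gave 0 to 397: 1, 161, 5 and 0 without null low-salt rats 2 to 5, 54 and 55 without null high-salt rats 3 and 5, 29, 53, 4 and 397 without SS low-salt rats 1 to 4, and 373 without SS high-salt rat 1. For the interaction it gave 221 to 612: 260 and 221 without null low-salt rats 4 and 5, 224, 237 and 267 without null high-salt rats 1, 4 and 5, and 237 without SS high-salt rat 2.

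Directions turned mostly in genes that had not passed. With total scaling the low-salt Ccl2 difference was 0.14, and for salt in SS Ifit2 was at 0.046, Atp6v1b1 0.088, Pdpn 0.024, Klf4 0.013, Msmo1 0.073, Fdft1 0.17, Sqle 0.052, Acta2 0.38, Kcnmb1 0.29, Nos3 0.35 and Slc34a1 0.37, and on low salt the copies of Acsm2 were at 0.031 and 0.022 and Fdps at 0.097. With the mitochondrial share as a covariate Mt-nd2 was at 0.47, Mt-atp6 0.24, Mt-cyb 0.10, Acta2 0.00044, Kcnmb1 0.27, Trpc6 -0.077 and Slc34a1 0.037, low-salt Ccl2 at 0.098 and the mitochondrial list for salt in null at 0.043, as the covariate removes that share. With quantile normalization Mt-co3 was at 0 and Mt-co2 at 0.068, Acta2 0.074, Trpc6 -0.11, Slc34a1 0.41 and low-salt Ccr2 -0.017. It also turned the set test of the proximal tubule list for salt in SS, whose mean kept its sign (-0.22 in the main fit, -0.017 here). With the tubule score Npr1 was at -0.022, Myh11 -0.28, Cacna1c -0.29, Ednra -0.18, Slc34a1 0.30, low-salt Ccr2 -0.037 and in the interaction Hadh -0.033. It turned the set test of the proximal tubule list (means 0.19 for salt in SS, -0.0196 for genotype on high salt, 0.042 for the interaction), the collecting duct list (-0.017 and -0.025 for salt in SS and the interaction) and the fatty acid list (-0.032 and -0.11 for genotype on high salt and the interaction). The means of the proximal tubule list in the interaction and of the collecting duct list for salt in SS kept their sign and shrank. For the proximal tubule and collecting duct lists such changes were largely built in, as the score is made from their genes. Library weights put Acta2 at 0.032, Trpc6 -0.11 and Nos3 0.035, and scaling without mitochondrial genes put Acta2 at 0.061, Nos3 0.031 and Slc34a1 0.053. Without the 2 libraries Acta2 was at 0.071, Kcnmb1 0.050, Trpc6 -0.10 and Slc34a1 0.010, and Trpc6 was at -0.0088 with edgeR and -0.017 with DESeq2. Without single rats Acta2 ranged from -0.061 to 0.071, Myh11 from -0.074 to 0.20, Kcnmb1 from -0.21 to 0.050, Trpc6 from -0.10 to 0.20, Nos3 from -0.11 to 0.041, Agtr1a from -0.0011 to 0.24, Slc34a1 from -0.092 to 0.030 and low-salt Ccr2 from -0.040 to 0.16.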

Other observations

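Genes of the circadian clock were higher on high salt in rats labelled null than in SS rats in 4 of 17 cases, Per3 by 1.07 ± 0.33, Per2 by 0.84 ± 0.21, Hlf by 0.80 ± 0.23 and Clock by 0.39 ± 0.10 (adjusted p = 0.239 with an estimated correlation). The hour of dissection is not given in the sources used here. The chaperones Hsph1 (0.88 ± 0.20), Hsp90aa1 (0.66 ± 0.18), Dnaja1 (0.58 ± 0.17) and Hspa8 (0.53 ± 0.15) were higher in the same comparison, and the immediate early genes Egr2 (-1.29 ± 0.30) and Atf3 (-1.06 ± 0.30) lower. For these lists the adjusted p was 0.391 and 0.458 with an estimated correlation. In SS rats Egr2 rose with salt (1.26 ± 0.30).

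Proximal tubule genes split in SS rats on high salt: Kap (-1.63 ± 0.21), Slc7a13 (-1.58 ± 0.27) and Gatm (-1.38 ± 0.24) fell and Cyp2e1 rose (1.02 ± 0.17), with 6 of 21 lower and 2 higher. In the collecting duct list Fxyd4 (-0.94 ± 0.20), Aqp4 (-0.69 ± 0.20) and Scnn1g (-0.53 ± 0.15) fell. The interferon genes Gbp5 (-0.62 ± 0.13) and Gbp2 (-0.39 ± 0.11) fell in SS rats and in rats labelled null (-0.52 ± 0.13 and -0.48 ± 0.11). For these 3 lists in SS rats the adjusted p was 0.656, 0.186 and 0.656 with an estimated correlation.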
